A study of Mus musculus with 16 samples.

How the data were processed

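RNA sequencing was done on lumbar spinal cords of 16 mice aged 150 days in 4 groups of 4. The design text gives the 4 animals of a group as biological replicates. Per the labels' protocols, RNA was extracted with Trizol and a column kit, enriched for poly-A RNA and made into libraries with the Illumina TruSeq RNA kit. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.4 and Cufflinks 2.0.2 were used with mm9, without a role for each. The tool that made the gene counts and whether it used strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes can have been assigned to either.

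The authors deposited raw counts of 23284 gene symbols, one column per library, which are whole numbers with library totals from 14989026 to 20892530. They also deposited FPKM values (scaled for transcript length and library size) in a table of all libraries and in 1 Cufflinks-style table per library. The 2 sources held identical FPKM values, compared with no tolerance, in all 23699 entries of each library. Gene positions come from the loci of those tables, in mm9, written from 1. The reference annotation supplied with the files is of another mouse build, and no coordinate was taken from it. Of the genes, 3312 had 0 counts in all libraries.

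Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test, with TMM normalisation and the default filterByExpr rule, which left 15426 genes. All 16 libraries entered 1 fit with a coefficient per group and no other covariate. The 5 comparisons were the transgene effect in cWT and in cKO, the cKO effect without and with the transgene, and their interaction. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene counted as changed at an adjusted p under 0.05. CPM values used TMM library sizes. The procedure was tested on negative binomial counts simulated from the fitted means and dispersions, of which 15313 genes passed the filter, with 50 genes changed at each of 4 sizes in the cWT_SOD1 libraries alone. For the transgene effect in cWT it recovered 50% of genes changed 1.3-fold, 64% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 8 false among 161 calls. For the cKO effect with the transgene the shares were 54%, 62%, 92% and 100%, with 5 false among 159 calls. For the interaction they were 26%, 48%, 72% and 92%, with 9 false among 128 calls. The simulation changed far fewer genes than were called in the data and gave all groups the same dispersion. These rates therefore need not hold for the comparisons here.

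Before the data were examined, 30 gene lists of cell types and pathways were fixed from general knowledge, and 551 of their 555 entries were matched, 6 of them through an older symbol. Each list was tested with limma 3.58.1 by camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, two-sided, beside fry and camera with an estimated correlation. A list score per library was the mean over members of log2 CPM minus the mean of the gene over all libraries. Scores were compared by two-sided exact permutation tests over the 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286, and for the interaction over the 4900 assignments of genotype labels within transgene status. The null of that interaction test is no genotype difference at either transgene status, so a real difference at either one widens its spread. P-values of lists were adjusted over the 30 lists within a comparison. At its smallest p, an exact test of 4 against 4 libraries passes this adjustment only where many lists reach that p together.

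Genes are named by a rule fixed before the data were examined. It takes Atg7 and Sod1, then up to 10 genes with the highest and 10 with the lowest log2 fold change among called genes with a mean of at least 1 CPM and no overlap between the 2 groups, the overlap not being asked of the interaction. It adds up to 4 members with the smallest p from each list described, and, where fewer than 5 genes are called, the 5 genes with the smallest p. Xist and Y-linked genes were left out and served only to read the sex of the animals. Which lists are described for which comparison, and the limit to the first 2 members of most lists, were chosen after the results were seen, and the spinal interneuron list (cKO with the transgene and interaction) and the interferon list (interaction) were added after their values were seen. All 4 members are given for motor neurons and for the cKO effect without the transgene.

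A fold against a group with 0 counts was taken against a floor of 3 counts over the group, and ratios of low counts carry a 95% counting interval. The labels name no molecular tags, so intervals and floors cover counting error only. Pairs of libraries within a group differed by more than sampling noise, at a mean chi-square per gene from 2.88 to 40.8, and none was counted as a duplicate.

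The alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 4 libraries, a fit of only the 8 libraries compared, the replicate number as a block, sex as a covariate, each library left out in turn, and limma on log2(FPKM + 0.1) and log2(FPKM + 1). The FPKM fits left out 248 duplicated symbols and 50 with a failed estimate, and used 16371 genes with a mean FPKM of at least 0.1, or 19606 without that filter. Fits of males only, of females only and limma-voom with 1 variance weight per group were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, isoforms and the human transgene transcript were not analysed here, and some genes that the naming rule takes are not reported here.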

Results

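The series measured gene expression by RNA sequencing in the lumbar spinal cord, the segment that holds the motor neurons of the hindlimbs, of mice 150 days old. Atg7 encodes the E1-like enzyme that the conjugation steps of autophagosome formation require, and the labels give the animals as Atg7 cKO, read here as conditional knockout, or Atg7 cWT, read as the wild-type counterpart. SOD1G93A is a mutant human SOD1 transgene used to model amyotrophic lateral sclerosis. The design crossed the 2 factors into 4 groups of 4 animals each, named cWT, cKO, cWT_SOD1 and cKO_SOD1. The title of the series places the autophagy inhibition in motor neurons, so the comparisons ask what that inhibition does to the cord with and without the transgene. Total counts ran from 14989026 to 20892530 per library, and 15426 of 23284 gene symbols had enough counts for testing. Counts of Xist and of Y-linked genes split every group into 2 males and 2 females. The first principal component held 71.4% of the variance and placed the groups at −37.6 ± 2.36 (cWT), −32.8 ± 5.12 (cKO), 72.4 ± 15.8 (cWT_SOD1) and −2.04 ± 1.71 (cKO_SOD1), and the second, with 5.55%, separated the sexes. Values below are TMM-normalised CPM (counts scaled to a common library size) as mean ± SD over the 4 libraries of a group. The standard error (SE) of a log2 fold change is an approximation. It is the size of the log2 fold change divided by the square root of its quasi-likelihood F statistic. Gene positions are mm9 gene spans, and each value is a whole-gene count. CPM are relative to the other RNA of the whole cord. A change of the cell mix or of the glial share therefore cannot be told apart from a change within cells.

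Atg7 (chromosome 6, 114593119 to 114810632) stood at 31.4 ± 2.51 CPM in cWT and 28.0 ± 1.06 CPM in cKO, a log2 fold change of −0.17 (SE 0.12, adjusted p = 0.9995) that was not distinguishable from the spread between animals. With the transgene the levels were 24.1 ± 4.26 CPM in cWT_SOD1 and 27.2 ± 4.50 CPM in cKO_SOD1, and the genotype difference was 0.17 (SE 0.12, adjusted p = 0.220). It passed the test at 0.30 without cWT_SOD1 replicate 1 (adjusted p = 0.0212), at 0.29 without cKO_SOD1 replicate 2 (adjusted p = 0.0211) and at 0.42 in a fit of females alone (adjusted p = 0.00344). In a fit of males alone its sign turned, at −0.067 (adjusted p = 0.817). The transgene effect on Atg7 was −0.04 in cKO (SE 0.12, adjusted p = 0.883), and its interaction of 0.34 (SE 0.17, adjusted p = 0.103) also passed in females and without either of those 2 libraries (0.58, 0.47 and 0.46, at adjusted p of 0.00692, 0.0109 and 0.0121). A deletion limited to a few cells, or one that leaves the rest of the transcript, need not lower a whole-cord count, so Atg7 counts could not check the genotype labels here. Mouse Sod1 (chromosome 16, 90220987 to 90226569) did not differ with the transgene in cWT, at −0.09 (SE 0.06, adjusted p = 0.222), or in cKO, at −0.18 (SE 0.06, adjusted p = 0.0880), although the second value passed when only those 8 libraries were fitted (adjusted p = 0.0173) or with limma-voom weighted by group (adjusted p = 0.0267). Between genotypes Sod1 differed by less than 0.01 without the transgene (adjusted p = 0.9995) and by −0.10 with it (adjusted p = 0.182), with an interaction of −0.09 (adjusted p = 0.399). The human transgene transcript itself was not analysed here.

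The first comparison, cWT_SOD1 against cWT, asks what the transgene does to a cord with intact Atg7. Microglial and astrocyte genes rose and motor neuron genes fell. Gpnmb, a transmembrane glycoprotein of macrophages and microglia, rose from 3.80 ± 1.29 to 599 ± 277 CPM, and the integrin Itgax from 0.605 ± 0.433 to 127 ± 36.4 CPM. The astrocyte filament gene Gfap (chromosome 11, 102748650 to 102758514) rose 8.98-fold, from 1429 ± 127 to 12834 ± 1258 CPM. Chodl (chromosome 16, 78931193 to 78951973), a marker of fast motor neurons, fell 15.3-fold, from 86.0 ± 9.02 to 5.63 ± 1.46 CPM (adjusted p = 1.301e-12). In all, 10221 genes changed at an adjusted p under 0.05, of which 5122 were higher and 5099 lower, and 1721 were higher and 646 lower by more than 2-fold.

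All 24 measured members of the disease-associated microglia list rose, with a median of 11.1-fold. They included Cst7, a cystatin of activated microglia, at 300-fold (adjusted p = 5.58e-12), and the tetraspanin Cd9 at 5.21-fold. The homeostatic microglia list rose as well, with 13 of 13 members higher and a median of 3.77-fold, among them the fractalkine receptor Cx3cr1 at 4.98-fold. All 14 complement genes rose, with a median of 8.19-fold, among them C1qa at 16.9-fold and the receptor subunit Itgam at 5.61-fold. The interferon response list had 25 of 25 members higher at a median of 3.50-fold, with the tetherin gene Bst2 at 6.92-fold and Irf9, part of the interferon-activated transcription complex, at 2.68-fold. In antigen presentation 15 of 17 members rose, with B2m at 5.93-fold and H2-K1 at 4.92-fold, although reads of H2 genes can be shared between near-identical copies. The reactive astrocyte list had 20 of 20 members higher at a median of 10.2-fold, with the oncostatin M receptor Osmr at 13.9-fold. Lysosomal genes rose in 29 of 35 cases and fell in 5, with the progranulin gene Grn at 10.5-fold and Laptm5 at 8.22-fold. All 17 cell cycle genes rose at a median of 3.84-fold, with Top2a at 12.1-fold and Mki67 at 10.9-fold. The counts adjusted over the list alone were the same for each of these 8 lists. Each passed limma's camera test with a preset correlation of 0.01, at adjusted p from 1.93e-13 to 2.06e-06. With an estimated correlation none passed, at an adjusted p = 0.160 for cell cycle and an adjusted p = 0.204 for the other 7. Scored per animal, each of the 8 lists was higher in the 4 cWT_SOD1 libraries than in the 4 cWT libraries, with an exact permutation p = 0.0286, the smallest that 70 assignments allow, and an adjusted p = 0.0330.

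Several of the largest ratios belonged to genes close to 0 without the transgene. Atp6v0d2, a subunit of the vacuolar proton pump, had 0 counts in cWT and 1125 in cWT_SOD1. That was 410-fold higher against a floor of 3 counts over the group, and the lower 95% counting limit of the ratio was 333. Wisp2 went from 4 to 1386 counts, a ratio of 379 with a 95% counting interval of 148 to 1392. The macrophage elastase Mmp12 went from 4 to 1057 counts, a ratio of 289 (interval 112 to 1062). Apoc2 had 1 count against 306, a ratio of 334 (interval 59.6 to 13253), and Serpinf2 had 3 against 416, a ratio of 152 (interval 51.5 to 738). These intervals and floors cover counting error only. The fitted log2 fold change rose from 8.38 to 9.68 for Wisp2 without cWT replicate 4, and without cWT replicate 2 from 7.99 to 9.30 for Mmp12, from 7.78 to 9.37 for Apoc2 and from 7.04 to 7.99 for Serpinf2. Timp1, an inhibitor of metalloproteinases, rose 125-fold, and Lilrb4, whose reads can be shared with Gp49a beside it, rose 120-fold.

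Of 14 measured motor neuron genes, 12 fell and 2 rose, with a median log2 fold change of −1.69. After Chodl, the metalloproteinase Mmp9, a marker of fast motor neurons, fell 5.07-fold from 21.01 ± 0.545 to 4.14 ± 0.378 CPM, and the vesicular acetylcholine transporter Slc18a3 fell 3.35-fold. The members that rose were Anxa4, at 3.21-fold, and Stk32a, the latter named after its value was seen. Among pan-neuronal and synaptic genes 23 of 26 fell (24 adjusted over the list alone), with Rbfox3, which encodes the neuronal nuclear antigen NeuN, 1.91-fold lower and the glycine receptor subunit Glra1 3.34-fold lower. Among spinal interneuron genes 18 of 28 fell and none rose, with the muscarinic receptor Chrm2 3.57-fold lower and Slc17a6, the vesicular glutamate transporter 2, 2.25-fold lower. Cholesterol synthesis genes fell in 21 of 22 cases, with the regulator Srebf2 1.79-fold lower. These 4 lists passed the camera test at adjusted p from 1.24e-09 to 2.89e-04, and none passed with an estimated correlation, at an adjusted p = 0.204 for each. Their per-animal scores were lower in cWT_SOD1 with an exact permutation p = 0.0286 (adjusted p = 0.0330). Other large falls were in the LIM homeobox gene Lhx4 (10.4-fold), the aquaporin Aqp6 (6.73-fold), Uts2d (6.52-fold), Kirrel2 (6.10-fold), the R-spondin receptor Lgr6 (5.72-fold) and Smyd1 (5.204-fold). Col19a1 and Gkn3 fell 5.39-fold and 6.41-fold, but the cWT mean of Col19a1, 50.4 ± 66.1 CPM, was set by cWT replicate 4, without which its log2 fold change was −0.90 (adjusted p = 5.93e-04) in place of −2.43, and limma-voom weighted by group did not call it (adjusted p = 0.0855). Without cWT_SOD1 replicate 1 the log2 fold change of Gkn3 was −3.66 in place of −2.68. In a fit of males alone Gkn3 lost its call, at −0.996 (adjusted p = 0.310).

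In the axon injury response list 18 of 24 genes rose and 3 fell (18 and 4 adjusted over the list alone), with the stress transcription factor Atf3 41.0-fold higher, from 1.17 ± 0.342 to 48.0 ± 9.37 CPM, and Gadd45a 3.33-fold higher. Unfolded protein and integrated stress response genes rose in 20 of 27 cases and fell in 2, with Edem1 2.36-fold and Ddit3, which encodes CHOP, 2.31-fold higher. Autophagy genes other than Atg7 moved less and in both directions, with 7 of 34 higher and 19 lower and a median log2 fold change of −0.18. The kinase gene Ulk1 was 1.48-fold lower and Atg9a 1.45-fold lower. Atg7 itself was 1.304-fold lower (adjusted p = 0.00839), a call it lost on unfiltered FPKM (adjusted p = 0.0596) and in a fit of males alone (adjusted p = 0.215). The camera adjusted p was 1.13e-04 for axon injury, 6.06e-04 for the stress response and 0.0367 for autophagy, and with an estimated correlation the adjusted p was 0.204, 0.275 and 0.254. All 3 scores differed with an exact permutation p = 0.0286 (adjusted p = 0.0330).

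**Figure D1:**
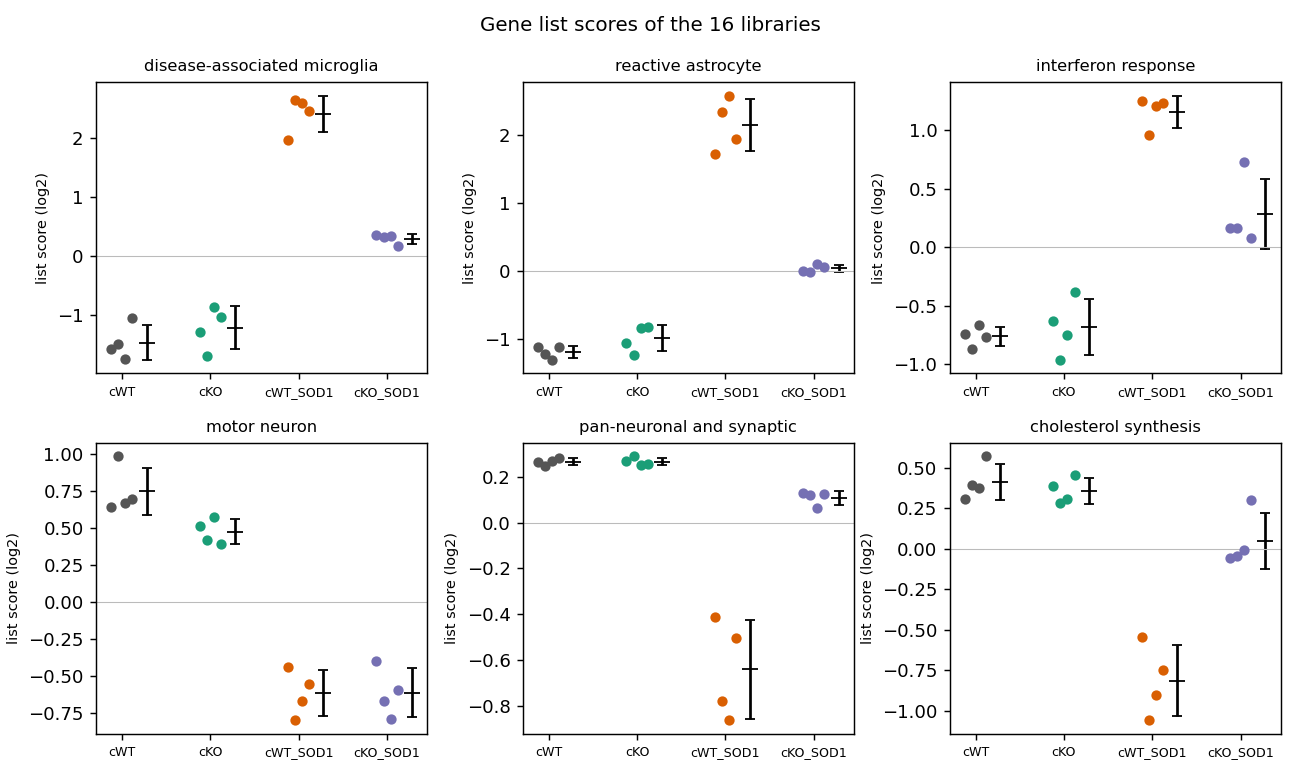
Scores of 6 gene lists in the 16 libraries, with the group on the horizontal axis and the score on the vertical axis, the mean over members of log2 CPM minus each gene's mean over all libraries. Points are single animals, and the bar and whiskers beside them are the mean ± SD of 4 libraries. The disease-associated microglia score was 2.41 ± 0.311 in cWT_SOD1 and 0.290 ± 0.0859 in cKO_SOD1, while the motor neuron score was −0.61 in each. Without Anxa4 and Stk32a, left out after their values were seen, the motor neuron score was −0.86 in cWT_SOD1 and −0.64 in cKO_SOD1.

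The same transgene in mice with the Atg7 deletion, cKO_SOD1 against cKO, gave a smaller set of calls, with motor neuron genes falling and microglial, interferon and astrocyte genes rising. Chodl fell 14.6-fold, from 51.1 ± 3.98 to 3.51 ± 0.682 CPM (adjusted p = 3.60e-11). Cst7 rose 16.2-fold, from 0.582 ± 0.487 to 9.48 ± 2.08 CPM, and Gfap rose 2.84-fold, from 1573 ± 204 to 4472 ± 259 CPM. In total 1123 genes changed, 740 higher and 383 lower, of which 235 and 26 passed 2-fold. The count was 2480 when only these 8 libraries were fitted, with 1235 higher and 1245 lower, and 2264 with limma-voom weighted by group, with 1217 higher and 1047 lower. It was 685 without cKO replicate 2, with 465 higher and 220 lower. Without cKO replicate 3 the log2 fold change of Cst7 was 4.62 in place of 4.01. With limma on log2(FPKM + 0.1) the split was 936 higher and 209 lower of 1145, so 81.7% were higher, and it was 798 and 210 of 1008 with a pseudocount of 1.

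Of the motor neuron genes 12 of 14 fell, with a median of 2.06-fold and none higher. Prph, which encodes the neuronal filament protein peripherin, fell 2.44-fold from 106 ± 10.1 to 43.2 ± 8.15 CPM, Slc18a3 fell 2.28-fold, Mmp9 fell 1.90-fold and the motor neuron homeobox gene Mnx1 fell 2.89-fold. The list passed camera at an adjusted p = 1.66e-16, and it also passed with an estimated correlation, at an adjusted p = 0.0345. Isl2, a LIM homeobox gene of motor neurons, fell 4.51-fold, the potassium channel Kcnj14 4.004-fold, the Wnt activator Rspo2 3.17-fold, the solute carrier Slc10a4 2.77-fold, Pde6b 3.98-fold and Cd24a 2.49-fold. Serpina3c fell 2.50-fold, and its reads can be shared with other members of the Serpina3 family. In single-sex fits Serpina3c lost its call in males (adjusted p = 0.141) and in females (0.282). Mnx1 and Mmp9 lost theirs in males (0.109 and 0.0677) and Pde6b in females (0.123).

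Of the disease-associated microglia genes 21 of 24 rose (22 adjusted over the list alone) with a median of 2.20-fold, and the dectin-1 gene Clec7a rose 7.87-fold from 2.58 ± 1.43 to 20.4 ± 4.29 CPM. The chemokine genes Ccl4 and Ccl3 rose 11.6-fold and 9.36-fold, and Ccl4 moved from a log2 fold change of 3.54 to 4.33 without cKO replicate 3. Of the interferon response genes 21 of 25 rose (22 adjusted over the list alone) with a median of 1.97-fold, among them the chemokine Cxcl10 at 9.76-fold and Irf9 at 1.60-fold. Complement genes rose in 9 of 14 cases (13 adjusted over the list alone), with C4b 3.05-fold and C3ar1 3.40-fold higher. Reactive astrocyte genes rose in 14 of 20 cases (17 adjusted over the list alone), with the hyaluronan receptor Cd44 2.36-fold higher. These 4 lists passed camera at adjusted p from 8.67e-24 to 9.94e-14. With an estimated correlation the adjusted p was 0.0576 for complement and 0.050004, not under the threshold, for the other 3. The small proline-rich protein gene Sprr1a, a marker of injured neurons, rose 10.3-fold. Serpinf2 went from 0 to 72 counts, 23.5-fold higher against a floor of 3 counts over the group, with a lower 95% counting limit of 18.7. Low counts also underlay the ratios of Cd200r4 (20.6, 95% counting interval 5.36 to 176), Cd300lb (11.4, 5.0002 to 32.2), Wisp2 (9.18, 4.92 to 19.0) and Gp49a (8.58, 4.12 to 20.7). On log2(FPKM + 1) Serpinf2, Cd200r4 and Cd300lb lost their calls (adjusted p = 0.0516, 0.200 and 0.0843), and Cd300lb moved from 3.42 to 4.41 on the log2 scale without cKO replicate 4. In a fit of males alone Serpinf2, Cd200r4, Ccl4, Cd300lb, Wisp2, Gp49a and Irf9 lost their calls (adjusted p from 0.109 to 0.487). Cd300lb also lost its call in females alone (adjusted p = 0.124).

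Of the pan-neuronal genes 3 of 26 fell, with the tubulin gene Tubb3 1.46-fold lower, while Rbfox3 was 1.15-fold lower at an adjusted p = 0.0289 that rose to between 0.0542 and 0.128 without any 1 of cKO replicates 1, 2 and 3 or of the 4 cKO_SOD1 libraries, and was 0.0769 on log2(FPKM + 0.1). Among spinal interneuron genes 1 of 28, Chrm2, fell (1.41-fold, adjusted p = 0.00858, or 0.0501 on log2(FPKM + 0.1)), and Calb2 was 1.26-fold lower without passing the test (adjusted p = 0.0764), although it passed without cWT_SOD1 replicate 1 (adjusted p = 0.0380), with DESeq2 (0.0420), with only the 8 libraries (7.36e-04), with the replicate block (0.0169) and with limma-voom weighted by group (0.0138). Of the cholesterol synthesis genes 3 of 22 fell (12 adjusted over the list alone), with Acat2 1.29-fold lower (adjusted p = 0.00513) and Dhcr7 1.27-fold lower (adjusted p = 0.0350). On log2(FPKM + 0.1) the adjusted p was 0.0572 for Acat2 and 0.112 for Dhcr7, and Dhcr7 also lost its call without any 1 of cKO replicates 1, 3 and 4 or cKO_SOD1 replicates 1, 2 and 3 (adjusted p from 0.0624 to 0.115). Tubb3, Rbfox3, Acat2 and Dhcr7 lost their calls in both single-sex fits (adjusted p from 0.0708 to 0.628), and Chrm2 in males (0.505). Camera called these 3 lists lower at adjusted p = 9.74e-06, 0.0347 and 1.76e-08, and with an estimated correlation the adjusted p was 0.327, 0.386 and 0.223. In exact permutation tests of the scores the pan-neuronal list differed by −0.16 (adjusted p = 0.0476), as did disease-associated microglia by 1.52, interferon by 0.97, complement by 1.06, reactive astrocyte by 1.03 and motor neuron by −1.09 at the same p. Spinal interneuron (adjusted p = 0.117) and cholesterol synthesis (adjusted p = 0.0857) did not pass that exact test. In all 18 of 30 scores passed, among them T and NK cells (1.06, from 5 testable genes), homeostatic microglia (0.69), cell cycle (0.59), antigen presentation (0.51), axon injury (0.49), lysosome (0.44), meninges and fibroblasts (0.32), NRF2 and metal response (0.20), oligodendrocyte precursors (0.18), homeostatic astrocytes (0.13), respiratory chain (−0.13) and neurofilament and axon (−0.40). With medians over members in place of means none of the 18 passed (exact adjusted p from 0.0536 to 0.357). The 6 described lists among the 18 stayed at the smallest possible exact p of 0.0286. They lost the call only through the adjustment over lists.

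Without the transgene, cKO against cWT asks what the Atg7 deletion does by itself, and 4 genes changed. Fgf21 (chromosome 7, 52869260 to 52870860), a secreted fibroblast growth factor that other tissues release under metabolic stress, rose from 0.0815 ± 0.0294 to 4.97 ± 1.07 CPM (adjusted p = 2.52e-08). That was 6 counts against 381 over 4 libraries each, a ratio of 60.9 with a 95% counting interval of 27.7 to 167. Mmp9 fell 1.76-fold, from 21.01 ± 0.545 to 11.9 ± 0.987 CPM (adjusted p = 1.77e-04). Chodl fell 1.68-fold, from 86.0 ± 9.02 to 51.1 ± 3.98 CPM (adjusted p = 0.0113), and Mrvi1 (chromosome 7, 118011781 to 118125609) fell 1.59-fold, from 17.4 ± 0.545 to 10.9 ± 1.303 CPM (adjusted p = 0.00712). The next gene by p-value, Layn, was 1.52-fold lower (adjusted p = 0.0820), and it passed without cWT_SOD1 replicate 1 (adjusted p = 0.0377), with DESeq2 (0.00152) and with limma-voom weighted by group (0.0185). DESeq2 called 18 genes, 543 had an unadjusted edgeR p under 0.05, and on log2(FPKM + 0.1) the split was 3 higher and 1 lower where the counts gave 1 and 3. Chodl lost its call on those FPKM values (adjusted p = 0.252, or 0.0419 with a pseudocount of 1) and without any 1 of cWT replicates 2 and 3 and cKO replicates 1, 2 and 4 (adjusted p from 0.0692 to 0.114), and Mrvi1 lost it there too (adjusted p = 0.0620, or 0.0189 with a pseudocount of 1) and without cKO replicate 2 (adjusted p = 0.0629).

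Among 14 motor neuron genes Mmp9 and Chodl fell (4 genes adjusted over the list alone), and Slc18a3 and the acetylcholine-synthesising enzyme gene Chat were 1.299-fold and 1.41-fold lower without passing over all genes (adjusted p = 0.895 each). The list's median log2 fold change was −0.26 and camera called it lower at an adjusted p = 1.39e-06, against an adjusted p = 0.549 with an estimated correlation. Its score was lower by 0.27 with an exact permutation p = 0.0286, or an adjusted p = 0.429 over the 30 lists. No member of the unfolded protein and integrated stress response list passed over all genes, and 2 of 27 did adjusted over the list alone. Chac1, a stress-induced glutathione-degrading enzyme, was 1.52-fold higher (adjusted p = 0.0820), Atf4, the transcription factor of the integrated stress response, 1.14-fold higher (adjusted p = 0.123), Mthfd2 1.29-fold and Asns 1.09-fold. DESeq2 called Chac1 (adjusted p = 0.00107) and Atf4 (adjusted p = 0.00140), as did limma-voom weighted by group (0.0187 and 0.0478). Chac1 also passed on log2(FPKM + 0.1) (adjusted p = 0.0446), with only the 8 libraries (0.0210) and without cWT_SOD1 replicate 1 (0.00672). Of 24 axon injury genes none passed over all genes and 2 did adjusted over the list alone, with log2 fold changes of 0.76 (SE 0.25) for Atf3, 4.12 (SE 1.21) for Mmp12 and 1.25 (SE 0.56) for Sprr1a. Mmp12 had 57, 1, 14 and 9 counts in the cKO libraries, and its value was 2.79 without cKO replicate 1 and 5.44 without cWT replicate 2. Camera called these 2 lists higher at an adjusted p = 0.00669 each, and with an estimated correlation the adjusted p was 0.833 for the stress response and 0.729 for axon injury. In all camera called 8 of 30 lists and none with an estimated correlation. The other 5 were disease-associated microglia (adjusted p = 0.00669), cell cycle (0.0132), reactive astrocyte (0.0278) and complement (0.0492), called higher, and mitochondrial respiratory chain (0.00669), called lower, with no member past the test over all genes in any of them. No list score passed in this comparison (smallest exact adjusted p = 0.429). The motor neuron list and the neurofilament and axon list reached the smallest exact permutation p of 0.0286. A change confined to so few lists could not pass the adjustment, so its absence here is no evidence against one. None of 34 autophagy genes passed over all genes, and 1 did adjusted over the list alone. Sqstm1, which encodes the autophagy receptor p62, stood at 513 ± 21.8 CPM in cWT and 589 ± 24.2 CPM in cKO (adjusted p = 0.653; DESeq2 adjusted p = 0.0157). Map1lc3a, Atg12 and Map1lc3b had log2 fold changes of −0.18, −0.11 and −0.08 (adjusted p = 0.9995 each).

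**Figure D2:**
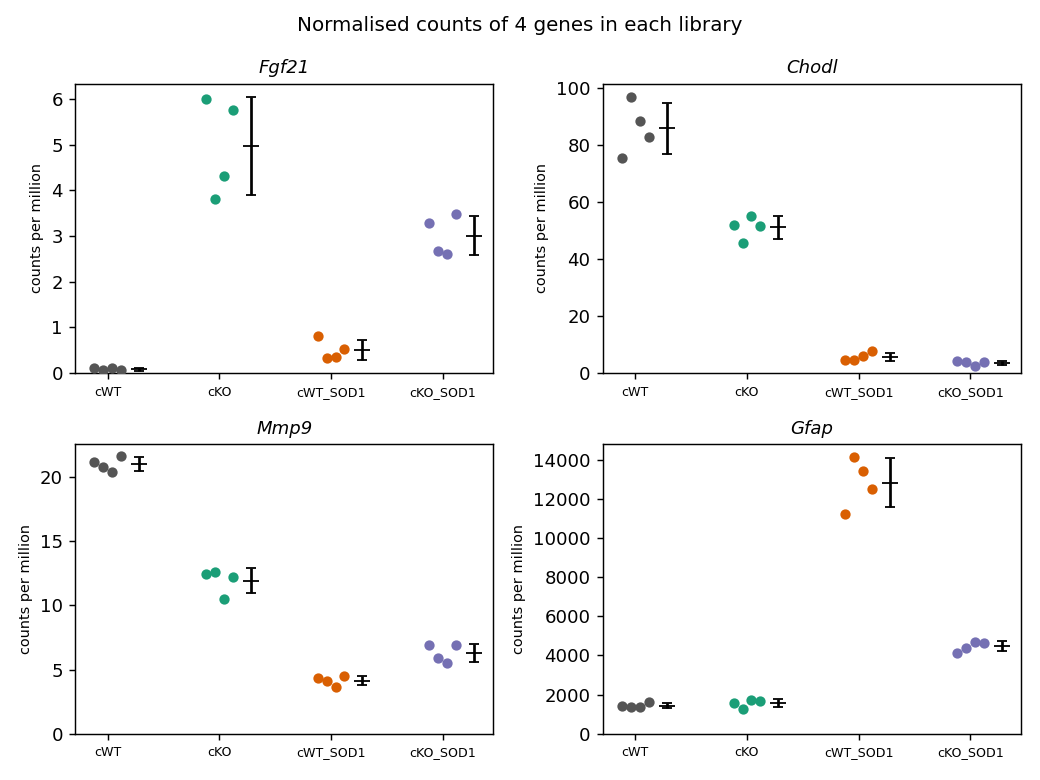
CPM of Fgf21, Chodl, Mmp9 and Gfap on linear vertical axes, by group on the horizontal axis. Points are single animals, with the mean ± SD of 4 libraries beside them. Fgf21 stood at 4.97 ± 1.07 CPM in cKO and 0.0815 ± 0.0294 CPM in cWT, and Chodl at 5.63 ± 1.46 CPM in cWT_SOD1 and 3.51 ± 0.682 CPM in cKO_SOD1.

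With the transgene, cKO_SOD1 against cWT_SOD1 asks how the Atg7 deletion alters the diseased cord, and microglial and reactive astrocyte genes were lower and pan-neuronal and spinal interneuron genes higher in cKO_SOD1. These are relative levels, and Gfap alone held 1.18% to 1.43% of counts in cWT_SOD1 and 0.417% to 0.483% in cKO_SOD1. Higher neuronal values therefore cannot be told apart from a smaller share of glial RNA. Gpnmb was 20.9-fold lower, at 28.7 ± 4.08 against 599 ± 277 CPM, and the acute-phase gene Serpina3n, a marker of reactive astrocytes, was 7.39-fold lower, at 258 ± 28.8 against 1909.7 ± 556 CPM (adjusted p = 1.48e-09). Glra1 was 2.73-fold higher, at 141 ± 3.44 against 51.6 ± 13.3 CPM. Among called genes with a mean of at least 1 CPM and no overlap between the groups, Fgf21 had the highest fold change, at 3.01 ± 0.436 against 0.501 ± 0.219 CPM, or 233 against 33 counts (6.002-fold, adjusted p = 2.34e-07). In all 8984 genes differed, 4488 higher and 4496 lower in cKO_SOD1, and beyond 2-fold 278 were higher and 1191 lower.

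All 24 disease-associated microglia genes were lower in cKO_SOD1, with a median of 4.18-fold, including Cd63 at 3.33-fold and Cd9 at 2.99-fold. All 20 reactive astrocyte genes were lower, with a median of 3.87-fold and S100a10 at 2.93-fold. All 14 complement genes were lower, with a median of 3.76-fold, C1qa at 6.56-fold and Itgam at 3.29-fold. Interferon response genes were lower in 21 of 25 cases (22 adjusted over the list alone), with Bst2 at 3.42-fold and Ifitm3 at 2.45-fold. Lysosomal genes were lower in 28 of 35 cases and higher in 2 (29 and 4 adjusted over the list alone), with Grn at 4.42-fold. These 5 lists passed camera at adjusted p from 6.67e-12 to 9.82e-06. With an estimated correlation the adjusted p was 0.3003 for interferon and 0.199 for the other 4. Scores of other cell types and of the cell cycle were lower as well, by exact permutation tests at an adjusted p = 0.0357 each, with differences of −1.14 for homeostatic microglia, −1.24 for T and NK cells, −1.08 for cell cycle, −0.44 for ependyma, −0.34 for homeostatic astrocytes and −0.25 for oligodendrocyte precursors. The T and NK cell score rests on 5 testable genes, among them Thy1, which is also in the pan-neuronal list. Among the 10 genes with the lowest fold changes were Igfbpl1 (22.1-fold lower), Slc43a3 (15.7-fold), the thyroid hormone-binding protein gene Crym (14.997-fold), Ppl (14.1-fold) and Serpina3i (15.1-fold, with reads that can be shared in its family). Serpina3i moved from −3.92 to −4.87 on the log2 scale without cKO_SOD1 replicate 1. Atp6v0d2 had 45 against 1125 counts, a ratio of 0.0344 (95% counting interval 0.0250 to 0.0464). Tnfsf11, which encodes RANKL, had 23 against 409, a ratio of 0.0484 (0.0303 to 0.0736). The ratios were 0.0639 for Wisp2 (0.0518 to 0.0781) and 0.0647 for Apoc2 (0.0404 to 0.0988).

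Pan-neuronal and synaptic genes were higher in cKO_SOD1 in 25 of 26 cases, with a median of 1.72-fold and Rbfox3 at 1.64-fold. Spinal interneuron genes were higher in 16 of 28 cases and lower in none, with Chrm2 at 2.46-fold and Slc17a6 at 2.17-fold, and with the interneuron homeobox gene En1 at 3.29-fold. Cholesterol synthesis genes were higher in 21 of 22 cases, with Srebf2 at 1.67-fold. Camera called these 3 lists at adjusted p from 1.94e-10 to 7.97e-05, and with an estimated correlation the adjusted p was 0.199, 0.199 and 0.269. Other genes far above their cWT_SOD1 level were Myoc (4.65-fold), Frem3 (4.38-fold), the muscle ubiquitin ligase adaptor Fbxo40 (4.17-fold), Lhx4 (4.09-fold), the homeobox gene Pou4f2 (3.59-fold), A930006I01Rik (3.44-fold) and Lgr6 (3.27-fold). Without cWT_SOD1 replicate 1 the log2 fold change of Fbxo40 was 2.68 in place of 2.06. Autophagy genes other than Atg7 were higher in 14 of 34 cases and lower in 7 (15 and 7 adjusted over the list alone), with Atg9a 1.45-fold and Ulk1 1.35-fold higher, and camera did not call the list (adjusted p = 0.172). In exact permutation tests of the scores each of these lists differed at p = 0.0286 (adjusted p = 0.0357), autophagy by 0.07.

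Motor neuron genes gave no common direction. Of 14 members 5 were higher, among them Mmp9 at 1.52-fold and the choline transporter Slc5a7 at 1.72-fold, and 4 were lower, among them Anxa4 at 2.70-fold and Stk32a at 2.46-fold. The median log2 fold change was 0.02 and the mean −0.01, the camera adjusted p was 0.855, and the score differed by less than 0.01 (exact permutation p = 1). The sign of that score difference turned with RLE or upper-quartile scaling. Without Anxa4 and Stk32a, left out after their values were seen, the score was −0.86 in cWT_SOD1 and −0.64 in cKO_SOD1. That difference was 0.225 (exact permutation p = 0.2).

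**Figure D3:**
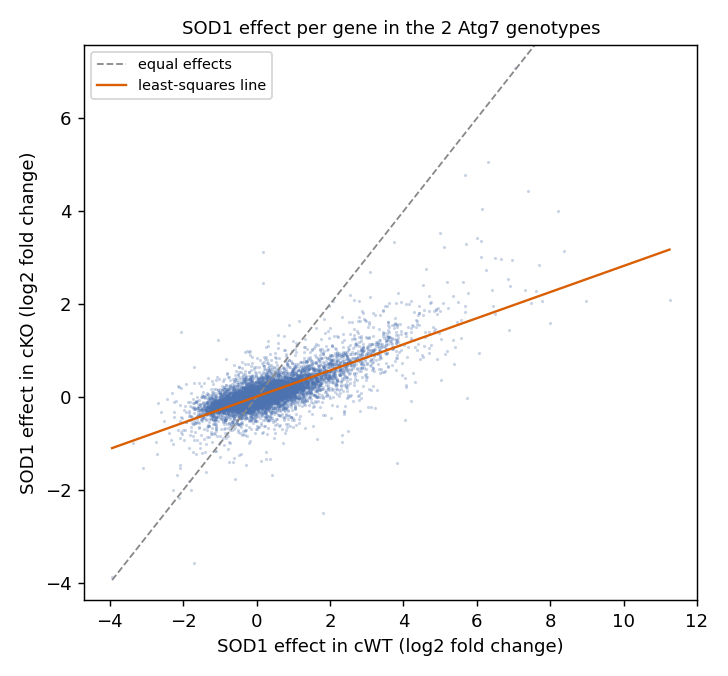
Log2 fold change of each of 15426 tested genes with the transgene in cWT on the horizontal axis and in cKO on the vertical axis. The dashed line marks equal effects and the solid line is the least-squares fit, whose slope was 0.281.

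Whether the transgene effect itself differed between Atg7 genotypes was tested as the interaction, and 6949 genes passed, 3582 with a higher and 3367 with a lower transgene effect in cKO. Across genes the transgene effect in cKO correlated with that in cWT at r = 0.769 with a slope of 0.281, as a description, since genes are not independent replicates. These were 0.329 and 0.194 with no filter on low counts, and 0.798 and 0.283 for genes with at least 1 CPM in 4 libraries. The 2 comparisons share no library. Of the 10221 genes called in cWT, 85.5% had the same sign in cKO, and the median ratio of the cKO to the cWT effect was 0.208. Both comparisons called 1094 genes, 1081 of them in one direction, with 729 higher in both where independent lists would give 246, and 352 lower in both where they would give 127. When the calling and the measuring used different libraries, the ratio of the median cKO effect to the median cWT effect, over genes past 2-fold, lay between 0.250 and 0.266.

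The interaction was negative for 23 of 24 disease-associated microglia genes, with log2 values of −1.67 (SE 0.12) for Cd9 and −1.95 (SE 0.16) for the cathepsin gene Ctsl. It was negative for 20 of 20 reactive astrocyte genes, with −3.00 (SE 0.22) for Serpina3n and −1.27 (SE 0.10) for S100a10. In the interferon list it was negative for 16 of 25 genes (18 adjusted over the list alone), with −1.38 (SE 0.21) for Ifitm3 and −0.75 (SE 0.13) for Irf9. It was positive for 23 of 26 pan-neuronal genes, with 1.504 (SE 0.17) for Glra1 and 0.73 (SE 0.08) for Rbfox3. Spinal interneuron genes were positive in 14 of 28 cases (15 adjusted over the list alone), with 1.34 (SE 0.16) for Chrm2 and 0.88 (SE 0.12) for the cholecystokinin gene Cck. Cholesterol synthesis genes were positive in 20 of 22 cases, with 0.75 (SE 0.09) for Srebf2. The camera adjusted p of these 6 lists ran from 1.18e-13 to 2.51e-04, and with an estimated correlation the adjusted p was 0.301 for interferon, 0.252 for cholesterol synthesis and 0.209 for the other 4. By permutation of genotype labels within transgene status, the score differences of the 6 lists had adjusted p from 0.0102 to 0.0367. Permuted within replicate numbers as well, none of the 6 passed (adjusted p from 0.0781 to 0.137).

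The motor neuron list did not pass the interaction test, with 6 of 14 members positive and 2 negative, a score difference of 0.27 (permutation p = 0.105) and a camera adjusted p = 0.244. Mmp9, at 1.42 (SE 0.13), and Slc5a7, at 0.90 (SE 0.19), were positive, and Anxa4, at −1.48 (SE 0.16), and Stk32a, at −1.15 (SE 0.24), were negative. Without Anxa4 and Stk32a, a choice made after their values were seen, the score difference was 0.53 (permutation p = 0.00776). Leaving out the 2 negative members favours a positive value, so no conclusion is drawn from that p. Single genes with the most negative values included Gpnmb at −5.01 (SE 0.57), Itgax at −4.86 (SE 0.75), the immunoglobulin receptor Fcgr4 at −5.13 (SE 0.74) and Rgs1 at −4.73 (SE 0.87), which was −6.56 without cWT replicate 4. The most positive included Lhx4 at 2.39 (SE 0.32), Myoc at 2.35 (SE 0.37), the Notch effector Heyl at 2.16 (SE 0.26) and Lgr6 at 2.01 (SE 0.20). In single-sex fits of 2 libraries per group, added after the data were seen, the number of interaction genes was 2863 in males and 4616 in females.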

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

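The tests of other splits of the libraries, of the neighbours of Fgf21 and of liver transcripts were set before their results were seen. The single-sex fits, the group-weighted limma-voom fit, the 3 tests of the microglial and astrocyte pattern and the test of a broad stress response were chosen only after the result was seen.

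The transgene effect differed between Atg7 genotypes for 6949 genes, and the list score of disease-associated microglia differed by −2.37 and that of reactive astrocytes by −2.32, both smaller effects in cKO. A cKO_SOD1 library without the transgene, or a cKO library labelled as one, is argued against, since the lowest disease-associated microglia score of the cKO_SOD1 libraries lay 1.03 above the highest of the cKO libraries, whose SD was 0.366. A wrong Atg7 label was not tested by this score. Fewer microglia alone, with no change of state, had been set to predict an equal log2 difference for both microglial scores, which was not met. The difference was larger for the disease-associated than for the homeostatic microglia score by −1.20 (SE 0.201). This test cannot exclude fewer microglia, since the 2 scores also rose unequally with the transgene in cWT, by 3.88 and 1.85. Over members, the slope through the origin of the cKO on the cWT effect was alike, at 0.406 and 0.367. A lower transgene dose in the cKO_SOD1 animals cannot be told apart, since mouse Sod1 did not rise with the transgene (−0.0865, SE 0.0610) and so carries no readout of it. The Atg7 deletion itself, which may act through a later or slower disease course at this single age, stays open as an untested biological hypothesis.

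Fgf21 went from 6 counts in cWT to 381 in cKO. Liver RNA in the cKO libraries is argued against, since the abundant liver transcripts Alb, Apoa1, Apoa2 and Serpina1c together gained 10 counts (95% upper limit 35.4) where Fgf21 gained 375. Reads running on from or into a neighbouring gene stay open, since Fut1 went from 3 to 27 counts, a log2 ratio of 3.11 (ratio 8.63, 95% counting interval 2.66 to 44.4), which met the bound set beforehand although 27 counts are few beside 381, while Izumo1 had 1 and 2 counts and Bcat2 and Rasip1 had log2 fold changes of −0.09 and 0.00. A broad integrated stress response cannot be told apart, since the list score was higher in cKO by 0.0921 with an exact permutation p = 0.114. A response of Fgf21 to the Atg7 deletion is therefore a hypothesis.

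The calls of each comparison were set against those of other splits of the same libraries, which cannot exclude chance. The best rank that 35 splits allow is 1 of 35, and it was not adjusted over the 5 comparisons. Splits that mix groups with large effects also widen the spread within the new groups, which lowers their calls. In 1 of 35 splits, the real one, as many genes were called, with 113 the highest other count for the transgene in cWT (real 10221), 7 for the transgene in cKO (real 1123), 0 for cKO without the transgene (real 4) and 709 for cKO with it (real 8984). The real split was also 1 of 35 in its correlation of the transgene effects, 0.769 against 0.633 for the highest other. For the interaction 2 of 100 drawn splits called as many, with 7106 the highest other. The 5 of the 100 that kept the real division of the transgenic libraries called 6606 to 7106 genes, and the others called 1 at most, so the count reflects the difference among the transgenic libraries.

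In all 22 of 30 list scores had a different transgene effect between genotypes (permutation adjusted p from 0.0102 to 0.0473). Beside the 2 above, those lower in cKO were complement (−2.03), cell cycle (−1.31), T and NK cells (−1.20, from 5 testable genes), lysosome (−1.19), homeostatic microglia (−1.17), axon injury (−1.11), antigen presentation (−1.09), interferon response (−0.96), NRF2 and metal response (−0.66), unfolded protein and integrated stress response (−0.61), meninges and fibroblasts (−0.53), homeostatic astrocytes (−0.32), heat shock (−0.29) and oligodendrocyte precursors (−0.24). Those higher were cholesterol synthesis (0.92), pan-neuronal and synaptic (0.75), neurofilament and axon (0.73), spinal interneuron (0.55), respiratory chain (0.26) and autophagy (0.08). Genes whose interaction passed the test with a higher value in cKO were Gkn3 (2.55), Col19a1 (2.40), Lhx4 (2.39), Myoc (2.35), Kirrel2 (2.29), Heyl (2.16), Sp7 (2.14), Lgr6 (2.01), Dmrt3 (2.005), Pcdha1 (1.86), Glra1 (1.504), Mmp9 (1.42), Chrm2 (1.34), Slc5a7 (0.90), Cck (0.88), Srebf2 (0.75) and Rbfox3 (0.73). Those with a lower value were Mmp12 (−6.39), Ctse (−5.44), Wisp2 (−5.24), Serpina3h (−5.23), Fcgr4 (−5.13), Gpnmb (−5.01), Itgax (−4.86), Rgs1 (−4.73), Serpina3n (−3.00), Ctsl (−1.95), Cd9 (−1.67), Anxa4 (−1.48), Ifitm3 (−1.38), S100a10 (−1.27), Stk32a (−1.15) and Irf9 (−0.75). Reads of Pcdha1 and Serpina3h can be shared within their families. Without cWT replicate 4 the value of Col19a1 was 0.87 (adjusted p = 0.0111). Gkn3 lost its call without cWT replicate 3, without cWT_SOD1 replicate 2 or 4, or without cKO_SOD1 replicate 2 or 4 (adjusted p from 0.0503 to 0.0684), and Ctse without cKO replicate 3 (adjusted p = 0.0785). Gkn3 was 3.54 without cWT_SOD1 replicate 1, Wisp2 −6.54 and Rgs1 −6.56 without cWT replicate 4, and Ctse −3.85 without cWT_SOD1 replicate 2 and −6.28 without cKO_SOD1 replicate 4. Mmp12 was −7.70 without cWT replicate 2 and −5.05 without cKO replicate 1. Serpina3h was −6.31 without cWT replicate 4, −4.52 without cWT_SOD1 replicate 3 and −7.49 without cKO_SOD1 replicate 1. With limma-voom the calls of Col19a1, Ctse and Serpina3h were lost (adjusted p = 0.119, 0.110 and 0.0576), and with limma-voom weighted by group those of Gkn3, Col19a1 and Sp7 (0.0820, 0.172 and 0.0627). Gkn3 was also lost on log2(FPKM + 0.1) (adjusted p = 0.0824, or 0.108 with no filter on low FPKM) and log2(FPKM + 1) (0.0755). In males alone Gkn3, Col19a1, Sp7, Dmrt3, Mmp12, Wisp2, Serpina3h, Fcgr4, Stk32a and Slc5a7 lost their calls (adjusted p from 0.0587 to 0.555), and in females alone Col19a1 (0.050022) and Ctse (0.201).

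A single library stood far from the other 3 of its group in 38 of 516 sets of 4 values tested (7.36%), where chance gives about 5%. Among list scores these were disease-associated microglia in cKO_SOD1 replicate 4 (0.162, others 0.325 to 0.345), interferon response in cWT_SOD1 replicate 2 (0.955) and cKO_SOD1 replicate 3 (0.732, others 0.0795 to 0.165), lysosome in cKO replicate 2 (−0.606), pan-neuronal in cKO_SOD1 replicate 3 (0.0628), cholesterol synthesis in cKO_SOD1 replicate 4 (0.301, others −0.0578 to −0.00836), the stress response in cWT_SOD1 replicate 1 (0.188, others 0.522 to 0.547) and autophagy in cWT_SOD1 replicate 2 (−0.113). In log2 CPM, cWT_SOD1 replicate 1 stood apart for Edem1 (6.25), Serpina3c (−0.0438), Dhcr7 (5.02), Chac1 (3.06), Map1lc3b (7.58), Frem3 (0.82), Stk32a (6.18) and Slc5a7 (6.31), and cWT_SOD1 replicate 3 for Smyd1 (1.41). The cKO_SOD1 libraries that stood apart were replicate 2 for Atg7 (4.36, others 4.88 to 4.89), Apoc2 (−0.79) and Serpina3c (−0.44), replicate 1 for Gkn3 (−1.54), replicate 3 for Anxa4 (3.88), Rbfox3 (7.05), Atg9a (6.96) and Rspo2 (2.17), and replicate 4 for Rgs1 (0.96). Among cWT libraries replicate 2 stood apart for Apoc2 (−2.59), Ulk1 (6.88), Kcnj14 (4.91) and A930006I01Rik (1.54), replicate 3 for Sprr1a (−0.85) and replicate 4 for Col19a1 (7.23, others 3.86 to 4.40). Among cKO libraries replicate 4 stood apart for Gkn3 (1.29), Pde6b (0.35), Sqstm1 (9.11) and A930006I01Rik (2.27), replicate 3 for Mmp9 (3.40) and replicate 2 for Ctsl (6.58).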

How the results depend on the processing

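The single-sex fits and the group-weighted limma-voom fit were chosen after the data were seen. Counts of called genes for the transgene in cWT and for cKO with the transgene stayed within 1.5 times under every alternative run, from 7595 to 10675 and from 6035 to 9335. For the transgene in cKO (1123) the count was 2480 with only the 8 libraries, 2264 with group weights, 91 in males and 362 in females, and 685 (without cKO replicate 2) to 1643 (without cWT_SOD1 replicate 1) with a library left out. For cKO without the transgene (4) it was 18 with DESeq2, 9 with only the 8 libraries, 10 with group weights, 1 in males and 2 in females, and 2 (without cKO replicate 2) to 9 (without cWT_SOD1 replicate 1). The interaction gave 2863 in males and 4616 in females, in fits of 2 libraries per group, and 6248 to 7654 with a library left out. Mmp9, Chodl and Mrvi1 lost their calls without the transgene in both single-sex fits, and Fgf21 kept its call in each fit run. The correlation of transgene effects (0.769) was 0.329 with no filter on low counts, 0.798 with 1 CPM in 4 libraries, 0.820 over called genes and 0.717 to 0.773 with a library left out. In the fit of all 16 libraries the spread of cWT_SOD1 also enters the comparisons that do not use that group. Its pairs of libraries reached a mean chi-square per gene of 40.8, against at most 11.6 in the other groups. The cause of these differences between fits was not tested.

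Values near 0 turned sign. Sod1 in cKO without the transgene was 0.11 in males and −0.0496 to 0.0282 with a library left out. Atg7 was −0.0667 in males for cKO with the transgene, and for the transgene in cKO it was 0.11 in females and −0.0853 to 0.0725 with a library left out. The motor neuron list in cKO with the transgene had an adjusted p = 0.972 downward with limma's fry and 0.570 to 0.996 with camera and a library left out, and its score difference was −0.0053 with RLE, −0.0036 with upper-quartile scaling and −0.0748 to 0.0568 with a library left out. With medians over members, all 18 of the 30 list scores that had passed for the transgene in cKO lost their call (exact adjusted p from 0.0536 to 0.357), while 22 of 26 kept it for the transgene in cWT, 21 of 24 for cKO with the transgene and 18 of 22 for the interaction. For the transgene in cKO, the 6 described lists that had passed stayed at the smallest possible exact p of 0.0286 and lost the call only through the adjustment. With a library left out, 240 of 240 score tests of the transgene in cWT passed, 139 of 160 of cKO with the transgene, 74 of 128 of the transgene in cKO and 92 of 112 of the interaction. With all libraries 15 of 15, 9 of 10, 6 of 8 and 6 of 7 of these lists had passed. The shares thus include lists that had not passed, and left-out libraries that a comparison of 2 groups does not use. Between 2 groups, permuting within replicate numbers has 16 assignments and cannot reach an exact p under 0.05 (smallest adjusted p = 0.139).

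The labels number the replicates 1 to 4 in each group, and the pairing was checked. Of 24 same-number pairs 11 had correlated deviations over 0.1 (−0.25 to 0.31). All 11 were pairs of the same sex, and every pair of different sex had a negative correlation. Of 16 libraries 7 correlated best with their own number, so the numbers were not taken as pairs. With the replicate number as a block the counts were 10204, 1158, 4, 9018 and 6936, and the correlation was 0.766. Of named genes the block changed only the call of Calb2 for the transgene in cKO (adjusted p = 0.0169). For the interaction scores, permutation within replicate numbers has 256 assignments, and none of the 30 lists passed it (smallest adjusted p = 0.0586), the 6 described lists that pass without the block having adjusted p from 0.0781 to 0.137. Depth limits genes under about 10 counts per group, whose ratios carry wide intervals.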

Other observations

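The tests of the motor neuron minus the pan-neuronal score were chosen only after the result was seen. Of the fixed lists not described above, several neuronal and metabolic ones moved with the transgene in cWT. Neurofilament and axon genes fell in 9 of 10 cases and rose in 1, with a median of 2.32-fold lower (camera adjusted p = 2.00e-04, adjusted p = 0.204 with an estimated correlation). Mitochondrial respiratory chain genes fell in 21 of 23 cases, with a median of 1.33-fold (camera adjusted p = 3.80e-06, adjusted p = 0.275 with an estimated correlation). The NRF2 and metal response list had 14 of 20 genes higher and 3 lower (camera adjusted p = 0.00195, adjusted p = 0.204 with an estimated correlation). In cKO_SOD1 against cWT_SOD1 the neurofilament list was higher in 9 of 10 cases and the respiratory chain list in 16 of 23, and the NRF2 list was lower in 14 of 20. The interaction of their scores was 0.73, 0.26 and −0.66, with permutation adjusted p of 0.0102, 0.0189 and 0.0331. Myelin and mature oligodendrocyte genes fell in 12 of 20 cases and rose in 3 with the transgene in cWT (camera adjusted p = 0.158). In cKO 1 of 20 rose and none fell. In cKO_SOD1 against cWT_SOD1 12 of 20 were higher and 3 lower (camera adjusted p = 0.0430, adjusted p = 0.447 with an estimated correlation), and the score was higher by 0.19 (exact adjusted p = 0.0357). With the transgene in cKO, neurofilament and axon genes fell in 6 of 10 cases, with a median of 1.29-fold (camera adjusted p = 2.36e-06, adjusted p = 0.118 with an estimated correlation), and their score fell by 0.40 (exact adjusted p = 0.0476).

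Markers of other cell types were also read with the transgene in cWT. Of 5 testable T and NK cell genes 4 rose and 1 fell (camera adjusted p = 0.151; score difference 2.26, exact adjusted p = 0.0330), and 12 members had too few counts. Homeostatic astrocyte genes rose in 8 of 16 cases and fell in 1 (camera adjusted p = 0.0384, adjusted p = 0.393 with an estimated correlation). Meninges and fibroblast genes rose in 7 of 11 cases (camera adjusted p = 0.0176, adjusted p = 0.393 with an estimated correlation). Ependyma genes rose in 6 of 9 cases (camera adjusted p = 0.0585), oligodendrocyte precursor genes in 7 of 13 with 3 lower (adjusted p = 0.125), Schwann cell and dorsal root genes in 4 of 8 (adjusted p = 0.188) and immediate early genes in 6 of 12 with 2 lower (adjusted p = 0.219). Endothelium genes rose in 2 of 12 cases (adjusted p = 0.826), no blood cell gene of 4 was called (adjusted p = 0.889), and of 3 testable skeletal muscle genes 1 fell (adjusted p = 0.279). In exact permutation tests of the scores, with an adjusted p = 0.0330 each, differences were 0.45 for homeostatic astrocytes, 0.85 for meninges and fibroblasts, 0.59 for ependyma, 0.42 for oligodendrocyte precursors, 0.61 for Schwann cells and dorsal root, and 0.56 for immediate early genes. Endothelium (0.04, adjusted p = 0.514), blood cells (0.53, adjusted p = 0.296) and skeletal muscle (−0.58, adjusted p = 0.0635) did not pass that exact test. Heat shock and chaperone genes rose in 5 of 16 cases and fell in 7, with a mean log2 fold change of 0.34 and a camera direction of lower (adjusted p = 0.976), while their score was higher by 0.32 (exact adjusted p = 0.0330). In cKO_SOD1 against cWT_SOD1 the scores of immediate early genes and of heat shock genes were lower, by −0.42 and −0.30 (exact adjusted p = 0.0357 each), while meninges and fibroblasts (−0.47, exact adjusted p = 0.0686), Schwann cells and dorsal root (−0.35, 0.159), blood cells (−0.40, 0.520), endothelium (less than 0.01 in size, 0.946) and skeletal muscle (0.38, 0.159) did not pass.

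A hypothesis formed after the data were seen, and tested only then, is that loss of motor neuron transcripts may proceed apart from the wider neuronal fall, since the motor neuron score fell by 1.09 in cKO with the transgene while the pan-neuronal score fell by 0.16. The motor neuron minus the pan-neuronal score was lower in cKO_SOD1 than in cWT_SOD1 by −0.748 (exact permutation p = 0.0286), but it was already lower by −0.273 in cKO without the transgene, and the interaction was −0.47 (permutation p = 0.160). Without Anxa4 and Stk32a, which rose with the transgene in cWT, that interaction was −0.21 (permutation p = 0.432). These permutations take no genotype difference at either transgene status as their null. The differences of −0.748 and −0.273 themselves widen that spread, so the large p-values do not count against an interaction. The hypothesis was therefore not decided.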
